A study of Mus musculus with 16 samples.

How the data were processed

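The series measured RNA from mouse OT-1 T cells on 16 Agilent 2-colour arrays. OT-1 cells carry a transgenic T cell receptor for the ovalbumin peptide SIINFEKL. Per the labels, lymph node cells of Rag-/- background, WT or Lck-/-, received 100 nM of this peptide for 24 h and 100 µg/ml cycloheximide for the last 10 min, which holds ribosomes on their mRNAs. Lysates without nuclei were spun on sucrose gradients of 10 to 50%. The first 5 fractions (1 to 5) were pooled as sub-polysomal RNA and the last 5 (6 to 10) as polysomal RNA. A fixed volume of 1.5 µl of each pool, not a fixed mass, was labelled. The labels do not say how much labelled RNA went onto an array. Each of the 8 extracts (4 WT, 4 Lck-/-) was measured on 2 arrays with the dyes swapped. The arrays sat on 2 slides, each with 8 arrays and 4 of each genotype.

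Per the file headers, the deposited scanner files hold spot and background values as intensity, made with Agilent Feature Extraction 10.7.3.1, with probe annotation on the mouse build mm9. They also hold processed values as intensity, from which the authors' software had removed background and dye bias. The deposited flags, of unit other (yes or no per spot), mark spots well above background, saturated spots and pixel outliers. The authors' table, with 8 columns, holds normalised log2 ratios of polysomal over sub-polysomal RNA, with the dye swaps combined and a single value missing. limma is named in the submitters' processing notes, with no version and no method of normalization.

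Each array had 62976 spots, of which 3671 were controls, and 55681 unique probes. Gene symbols were found for 31381 probes in the reference table of RefSeq genes, 27235 by accession, 3581 by symbol and 565 by synonym. These gave 22328 genes, and the 24300 probes without a gene were left out. Depth was counted as probes well above background per channel. The number of extracts limits the precision.

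Intensities were processed in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table. Mean spot intensities were corrected for median background with normexp and an offset of 50. The log2 ratios of each array were normalised with loess, with controls and outlier spots at weight 0, which sets the typical mRNA of each array to about 0. Levels of single channels were scaled between arrays with Aquantile. The 2 dye-swapped arrays of an extract were averaged, and the brightest probe stood for each gene. A gene entered the ratio comparison when its probe was well above background in both channels on at least 6 of 8 arrays of each genotype, and a level comparison when its channels passed in at least 1 genotype. The extract as labelled was the unit of every test, with n = 4 per genotype.

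The 4 comparisons between genotypes were the ratio, the mean of both fractions, the polysomal level and the sub-polysomal level, each as Lck-/- minus WT in log2. The ratio was also tested against 0 within each genotype. Linear models with empirical Bayes variances from limma gave p-values, adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. "SE" is the moderated standard error of a difference and "SD" the spread of the 4 extracts. Lists of genes (30 in all) were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, where at least 5 members were measured. Their members were also counted after adjusting p over the list alone. Values per extract were compared with exact permutation tests, two-sided, over 70 arrangements, of which the smallest possible p is 0.0286.

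Samples, comparisons, lists, filters and the first set of other settings were chosen before the data were examined. So was the rule for named genes. It takes Lck first, then the 10 largest rises and 10 largest falls of each comparison among genes with adjusted p below 0.05 and no overlap of the 4 and 4 extracts. It leaves out clone, transcript and predicted names and antigen receptor segments. It adds the 4 members with the smallest p of each list that passed, and the 10 highest and 10 lowest ratios in WT with all 4 extracts on the same side of 0. Of the genes taken by this rule, 2 are not reported here.

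The settings of the first set changed the background correction, the normalization within and between arrays, the filter, the probe per gene, the dye orientations used, the slide, the variance model and array weights, left out each extract in turn, set the replicate number as a block, took the sub-polysomal level as a covariate, and used the authors' ratios. Settings added after the data were examined exchanged the dye-swap arrays of WT replicates 1 and 2 (crossed dye swaps), left out these 2 extracts, left out probes with B1 or B2 SINE sequence, combined the exchange with leaving out these probes, kept the overall level of the ratio by leaving out normalization, and centred each column of the authors' table. SINE probes (163) were those that shared at least 5 stretches of 10 bases with B1 or B2 consensus sequences written from general knowledge. The overall level of the ratio, over the tested genes and over all probes, and a list of HIF-1 targets were also added after the data were examined. Classes of RNA followed the gene type and symbols in the reference table.

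The steps were tested on simulated data with the same arrays and known changes. For the ratio (8268 genes run), 52.2% of genes with a 1.5-fold change were called, 97.0% with a 2-fold and 100% with a 4-fold change. Of the calls, 9 were unchanged genes (5.14%). For the mean of both fractions (9075 genes run), these shares were 49.3%, 100% and 100%, with 11 unchanged genes called (5.79%). A list shifted on purpose there had an adjusted p of 1.75e-24, and 0 other lists were called. False calls from correlation within lists or from exchanged arrays were not tested. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.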

Results

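Polysomal and sub-polysomal RNA were compared in 8 extracts of OT-1 T cells, 4 from WT and 4 from Lck-/- cells, on 16 arrays. Lck is the Src-family kinase that starts signalling at the T cell receptor. Polysomal RNA holds mRNAs carrying several ribosomes, and sub-polysomal RNA holds mRNAs with few or none together with RNAs that are not translated. Each array set the 2 pools of 1 extract against each other, and a second array repeated the pair with the dyes swapped. Between 14619 and 50776 probes (median 20212.5) stood well above background in the polysomal channel of an array. In the sub-polysomal channel the range was 12531 to 30976 (median 22889), and no spot was saturated. The labels name the extracts as biological replicates but do not say whether they came from separate animals or cultures, so p-values measure only the spread between these samples.

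The arrays labelled as WT replicates 1 and 2 did not match their own dye swaps. Correlations of the deviations of log2 ratios from the genotype mean were -0.83 and -0.81 between the 2 arrays of each of these extracts, against 0.46 to 0.85 in the other 6 extracts. Between the 2 extracts they were 0.87 and 0.94. In the mean of both fractions such correlations were -0.02 and -0.18 within these extracts, and 0.52 and 0.38 between them. Values with these dye-swap arrays exchanged are called crossed dye swaps, an alternative chosen after the data were examined. Crossing leaves the mean of the 4 WT extracts as it is, apart from missing values, so it changes standard errors and p-values rather than differences. If the arrays were exchanged, each labelled average of these 2 extracts mixes both, and the labelled WT spread would be too small. Standard errors, p-values, counts and shares without overlap below use the labelled pairing unless another setting is named, and may then be too favourable.

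Lck itself was lower in Lck-/- cells but still well detected. In the mean of both fractions its log2 intensity was 15.03 ± 0.21 (SD, n = 4) in WT and 14.18 ± 0.13 (SD, n = 4) in Lck-/-, a difference of -0.85 (SE 0.14, limma adjusted p = 0.00297). The 4 Lck-/- extracts lay at 14.17, 14.35, 14.04 and 14.16 and the 4 WT extracts at 15.07, 15.16, 14.72 and 15.17. The probe lies on chromosome 4 of mm9, from 129225614 to 129225673 on the minus strand. The title of the series adds OFF to Lck-/-, and the labels do not say what this means or which part of the gene is changed. Why signal remained stays open. Lck fell by 0.91 in the polysomal level (SE 0.19, adjusted p = 0.0102) and by 0.79 in the sub-polysomal level (SE 0.12, adjusted p = 0.00270). With median centring the sub-polysomal difference of Lck was -0.28 with adjusted p = 0.238. Its ratio differed by -0.12 (SE 0.14, adjusted p = 0.675) after loess and by -1.14 with median centring, -1.15 without normalization and -1.53 in the authors' ratios, which keep the overall level.

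The first question is whether cells labelled Lck-/- differed from WT in how much mRNA sat on polysomes in general. Before normalization the median mRNA of Lck-/- extracts was less polysomal than that of WT extracts. The median log2 ratio was 1.35 ± 0.29 (SD, n = 4) in WT and 0.54 ± 0.28 (SD, n = 4) in Lck-/-, a difference of -0.82 with p = 0.0286 in an exact two-sided permutation test, the smallest p possible. WT extracts ranged from 1.06 to 1.74 and Lck-/- extracts from 0.21 to 0.80. The authors' deposited ratios gave 1.78 in WT and 0.59 in Lck-/-, a difference of -1.19 (exact permutation p = 0.0286). Over the tested genes the medians of the authors' WT columns were 1.53, 1.46, 2.53 and 1.59, and those of the Lck-/- columns 0.56, 0.65, 0.53 and 0.63. Over all probes the difference was -0.11 in the authors' columns (exact permutation p = 0.8) and 0.00 in the scanner files (exact permutation p = 1). Only 12466 to 27553 of the 55681 probes of an array stood well above background in both channels, so the median over all probes is set mostly by probes without signal and says nothing about the overall level. Each column matched the scanner files of 1 extract of its genotype (r 0.965 to 0.996) in direction, but their column numbers follow another order than the replicate numbers, and the centring and scale the authors used stay unknown.

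This overall result was chosen after the data were examined and rests on fixed volumes of RNA, so differences in the RNA yield of a pool or in labelling enter it. Arrays with the polysomal fraction in Cy5 alone gave -0.72 (exact permutation p = 0.0857), and those in Cy3 alone -0.91 (exact permutation p = 0.0286). On slide 1 alone the difference was -0.76 and on slide 2 alone -0.88. With genotypes exchanged only within a dye orientation these slides gave exact permutation p = 0.167 and 0.0556 over 36 arrangements, of which 0.0556 is the smallest possible p. That scheme was chosen after exchange over all arrays of a slide had given an exact permutation p of 0.429 on each slide, because each slide mixes orientations.

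**Figure D1:**
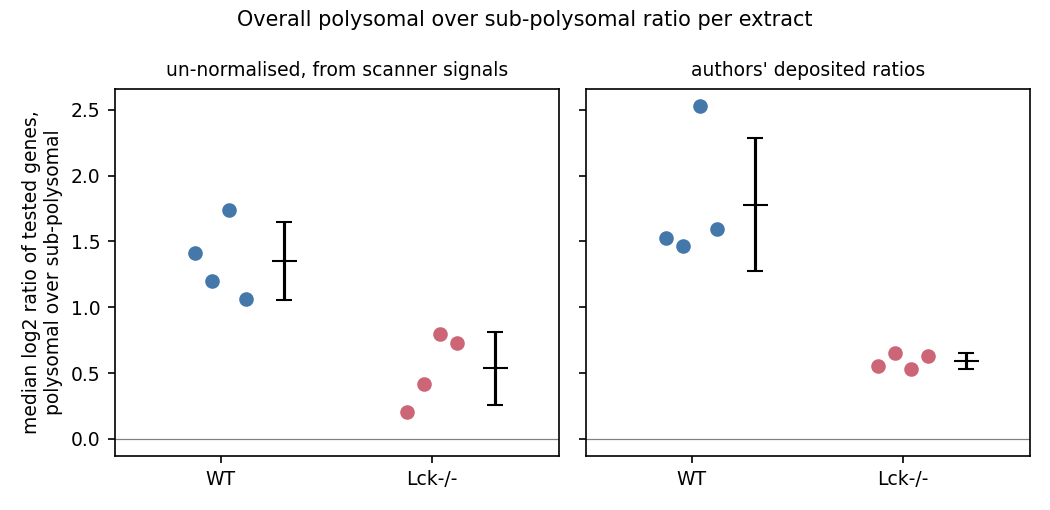
Median log2 ratio of polysomal over sub-polysomal signal per extract over the tested genes, before normalization (left) and in the authors' deposited columns (right), in WT and Lck-/-; points are extracts and bars are means ± SD. Before normalization the Lck-/- extracts lie between 0.21 and 0.80 and the WT extracts between 1.06 and 1.74.

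The second question is which mRNAs differed in polysome loading relative to the typical mRNA, after loess had set that mRNA to about 0. Messenger RNAs of cytosolic ribosomal proteins, which carry a terminal oligopyrimidine (TOP) start that ties their translation to growth signals, lay higher in the Lck-/- ratio. Of 81 measured ribosomal protein genes 51 rose and 0 fell (79 and 0 when adjusted over the list alone), with a median difference of 1.02. Rpl12 rose by 1.72 (SE 0.24, adjusted p = 0.00451), Rps15a by 1.53 (SE 0.18, adjusted p = 0.00165), Rps25 by 1.50 (SE 0.18, adjusted p = 0.00183) and Rps10 by 1.28 (SE 0.18, adjusted p = 0.00348). The list rose in camera (adjusted p = 3.61e-51), with adjusted p = 0.321 with an estimated correlation. The median of the list was 1.62 on slide 1, 0.40 on slide 2 and 1.02 with a slide term. It turned to -0.15 with median centring, -0.16 without normalization and -0.53 in the authors' ratios, and each of these lay above the median of all genes, at -0.78, -0.78 and -1.15.

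In Agilent's own processed signals the ribosomal protein list had a median of 0.13 and its call was lost (adjusted p = 0.101). The median ratio of these mRNAs per extract gave an exact permutation p of 0.0286, and 0.143 with crossed dye swaps. With crossing the differences of Rps15a, Rps25, Rps10 and Rpl12 stayed at 1.53, 1.50, 1.28 and 1.72, but their SE rose to 0.35, 0.53, 0.35 and 0.55 and their calls ended (adjusted p = 0.115, 0.436, 0.228 and 0.381). In the authors' ratios Rps25, Rps10 and Rpl12 turned to -0.02, -0.42 and -0.06.

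Other TOP mRNAs followed the same direction. Of 18 measured members of the list of elongation factors and other TOP mRNAs 7 rose and 0 fell (14 and 0 when adjusted over the list alone), with a median of 0.65. Tpt1, a growth-related TOP mRNA, rose by 1.42 (SE 0.18, adjusted p = 0.00216) and Eef1g, an elongation factor subunit, by 1.07 (SE 0.15, adjusted p = 0.00479). Pabpc1, the cytoplasmic poly(A)-binding protein, rose by 1.26 (SE 0.21, adjusted p = 0.00982) and Rack1, a protein of the small ribosomal subunit, by 0.84 (SE 0.14, adjusted p = 0.00909). The list rose in camera (adjusted p = 3.53e-11), with adjusted p = 0.321 with an estimated correlation, and its median was 0.99 on slide 1, 0.35 on slide 2 and 0.65 with a slide term. The list median turned to -0.46 with median centring, -0.48 without normalization and -0.75 in the authors' ratios, and the call was lost in Agilent's processed signals (0.12, adjusted p = 0.163). With crossed dye swaps Rack1 stayed at 0.84 (SE 0.18) and Pabpc1 at 1.26 (SE 0.26), and both calls ended (adjusted p = 0.0935).

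Nuclear-encoded genes of oxidative phosphorylation fell slightly as a list. Of 76 measured genes 0 rose and 1 fell (0 and 0 when adjusted over the list alone), with a median of -0.20, at -0.08 on slide 1, -0.34 on slide 2 and -0.20 with a slide term. Ndufb6, a subunit of complex I, fell by 0.55 (SE 0.12, adjusted p = 0.0274). Cycs, the electron carrier cytochrome c, stood at -0.80 (SE 0.20, adjusted p = 0.0551), Atp5j at -0.51 (SE 0.13, adjusted p = 0.0542) and Ndufab1 at -0.55 (SE 0.16, adjusted p = 0.0859). The list gave adjusted p = 0.00134 in camera, and adjusted p = 0.780 with an estimated correlation. Without Lck-/- replicate 2 its call was lost (adjusted p = 0.0693), and Ndufb6 lost its call without any of 6 extracts, with the highest adjusted p of 0.0997 without Lck-/- replicate 4, and with crossed dye swaps (-0.55, SE 0.15, adjusted p = 0.216).

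The mitosis list also fell in the ratio, with 0 of 27 measured genes up and 1 down (0 and 2 when adjusted over the list alone) and a median of -0.17. Top2a, the DNA topoisomerase of dividing cells, fell by 0.89 (SE 0.19, adjusted p = 0.0277). Mki67, the proliferation marker, stood at -0.78 (SE 0.19, adjusted p = 0.0512), Cdk1 at -0.57 (SE 0.21, adjusted p = 0.175) and Tpx2 at -0.48 (SE 0.17, adjusted p = 0.149). Camera gave adjusted p = 0.0372, or 0.823 with an estimated correlation. The median was -0.39 on slide 1, 0.12 on slide 2 and -0.17 with a slide term. The call was lost with crossed dye swaps (adjusted p = 0.0883), in processed signals (adjusted p = 0.0688), without Lck-/- replicate 2 (adjusted p = 0.124) and without WT replicate 3 (adjusted p = 0.122).

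Across all 8266 genes tested for the ratio 231 rose and 88 fell, and 161 rises but 0 falls were at least 2-fold. The 10 largest rises were Exosc2 at 2.72 (SE 0.29), Milr1 at 2.67 (SE 0.29), Pbld1 at 2.55 (SE 0.28), Synrg at 2.53 (SE 0.29), Medag at 2.43 (SE 0.28), Zfp408 at 2.43 (SE 0.28), Pirb at 2.39 (SE 0.27), Mfsd2b at 2.38 (SE 0.27), Coa8 at 2.37 (SE 0.28) and Lrrc31 at 2.36 (SE 0.29), each with adjusted p between 0.00162 and 0.00183. The probes of all 10 hold sequence of B1 or B2 SINEs, short repeats found in many RNAs, so these values need not come from the named genes. Without SINE probes Milr1 read 0.12 (adjusted p = 0.677) and Synrg 0.35 (adjusted p = 0.388) from another probe.

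The 10 largest falls of the ratio were smaller. Gtf3a, the transcription factor of 5S ribosomal RNA genes, fell by 0.91 (SE 0.17, adjusted p = 0.0160), Ssu72, a phosphatase of RNA polymerase II, by 0.85 (SE 0.16, adjusted p = 0.0190), and Tfg by 0.84 (SE 0.15, adjusted p = 0.0150). Tmem14c fell by 0.80 (SE 0.19, adjusted p = 0.0476), the peroxiredoxin Prdx1 by 0.78 (SE 0.16, adjusted p = 0.0219), Cyb5r3 by 0.76 (SE 0.17, adjusted p = 0.0344), Lbh by 0.76 (SE 0.18, adjusted p = 0.0433), Sf3b6, a spliceosome subunit, by 0.74 (SE 0.18, adjusted p = 0.0487), and St8sia4, a polysialyltransferase, by 0.74 (SE 0.14, adjusted p = 0.0160), with Top2a as the tenth at -0.89. With crossed dye swaps the 10 differences stayed the same, but SE rose to between 0.16 for St8sia4 and 0.54 for Gtf3a and all 10 calls ended, with adjusted p from 0.0935 for Tfg to 0.660 for Gtf3a. Each was also lost on leaving out any of 2 to 7 extracts, and the highest values follow. Without Lck-/- replicate 4 adjusted p was 0.0566 for Gtf3a, 0.0754 for Prdx1, 0.108 for Cyb5r3 and 0.144 for Sf3b6. Without Lck-/- replicate 3 it was 0.0569 for Tfg, 0.0630 for Ssu72, 0.129 for Lbh and 0.129 for Tmem14c. Top2a was lost without WT replicate 2 (adjusted p = 0.0848) and St8sia4 without WT replicate 1 (adjusted p = 0.0591).

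By class of RNA, those far from polysomes in WT lay closer to the typical mRNA in Lck-/-. The 13 mRNAs encoded by mitochondrial DNA, which are translated inside mitochondria, had a median ratio of -3.86 in WT and -1.74 in Lck-/-, and 9 rose. Ribosomal protein mRNAs went from -1.35 to -0.41. Of 61 genes read by sense SINE probes 48 rose (median difference 1.32), and of 14 read by antisense ones 5 rose (0.70). Of 183 pseudogenes 50 rose and 1 fell (0.42), but whether their probes read other genes was not tested. Of 123 non-coding RNAs 11 rose (0.26). Of the other 7787 protein-coding genes 57 rose and 87 fell (-0.05). The medians per extract gave exact permutation p = 0.0286 for mitochondrial mRNAs and sense SINE probes, labelled or crossed. For pseudogenes the exact permutation p was 0.0286 and 0.229 when crossed, for antisense SINE probes 0.0571 and 0.0571, for non-coding RNAs 0.0857 and 0.0571, for ribosomal protein mRNAs 0.0286 and 0.143, and for other protein-coding genes 0.0571 and 0.229.

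**Figure D2:**
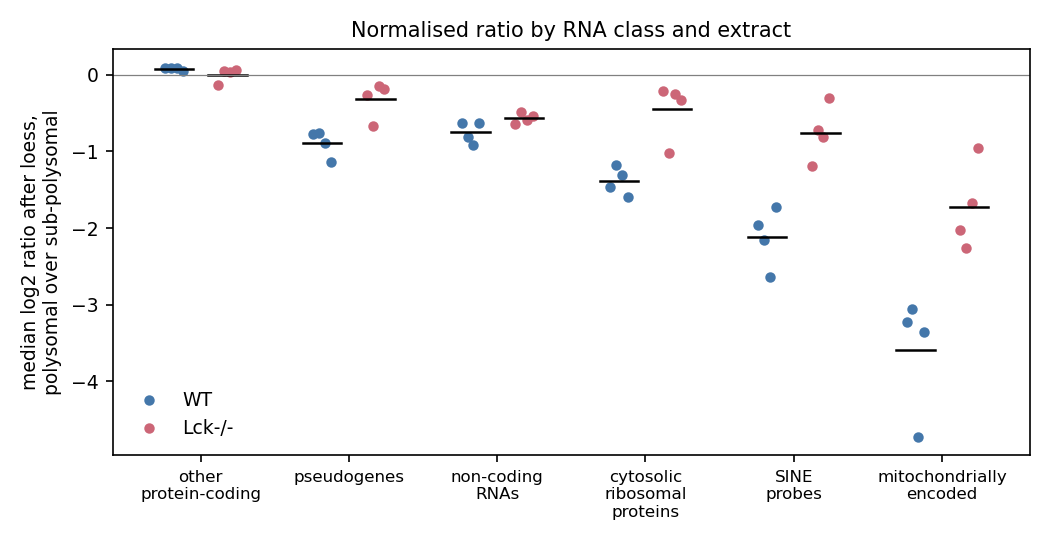
Median log2 ratio of polysomal over sub-polysomal signal per extract after loess for 6 classes of RNA in WT and Lck-/-. Points are extracts with dye swaps as labelled and bars are means of 4. With crossed dye swaps the ribosomal protein medians of WT replicates 1 and 2 were -2.22 and -0.205. Mitochondrially encoded mRNAs have class medians of -3.86 in WT and -1.74 in Lck-/-, and ribosomal protein mRNAs -1.35 and -0.41 after loess; the difference of the ribosomal protein list turns to -0.15 with median centring, -0.16 without normalization and -0.53 in the authors' ratios.

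The number of ratio calls depended on the pairing of arrays, the extracts and the scaling. With crossed dye swaps 40 genes rose and 0 fell, with 755 genes at unadjusted p below 0.05, and without WT replicates 1 and 2 the counts were 83 and 2. On leaving out 1 extract the total of 319 became 103 without Lck-/- replicate 3, 105 without Lck-/- replicate 4, 114 without WT replicate 1, 176 without WT replicate 2 and 156 without WT replicate 3. The 231 rises and 88 falls became 33 and 4682 with median centring, 39 and 5948 without normalization, 25 and 7427 in the authors' ratios and 444 and 289 in the authors' ratios with each column centred. The median of all genes was -0.04 with loess and -0.78, -0.78, -1.15 and 0.03 in these 4. Slide 1 alone called 184 rises and 4 falls and slide 2 alone 35 and 2, and all 16 arrays with slide and dye terms 225 and 162. No overlap of the 4 and 4 extracts was seen in 1183 genes (14.4%), where chance gives 2.86%, and in 305 of the 319 called. Tested as the polysomal level with the sub-polysomal level as covariate in limma, 0 genes passed and 1440 had unadjusted p below 0.05. The remaining 21 tested lists did not pass, with adjusted p from 0.0604 for mitochondrial ribosomal proteins to 0.953 and medians from -0.13 to 0.22, and 9 of their genes rose and 5 fell.

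The third question is which RNAs differed in the mean of both fractions, which a shift between them can move at a constant amount. Cell division genes fell furthest in Lck-/- cells. Of 35 measured mitosis genes 29 fell and 0 rose (30 and 0 when adjusted over the list alone), with a median of -1.03. Anln, a scaffold of the cleavage furrow, fell by 1.38 (SE 0.15, adjusted p = 0.000526), Espl1, the separase that parts chromatids, by 1.17 (SE 0.14, adjusted p = 0.000747), Cdk1, the kinase that drives entry into mitosis, by 1.16 (SE 0.12, adjusted p = 0.000421) and Bub1, a spindle checkpoint kinase, by 1.13 (SE 0.12, adjusted p = 0.000357). The list fell in camera (adjusted p = 1.12e-17, or 0.437 with an estimated correlation). Its medians were -1.07 on slide 1, -1.04 on slide 2 and -1.03 with a slide term.

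Replication-dependent histone genes, which are expressed in S phase, fell in 11 of 18 measured cases and rose in 0 (16 and 0 when adjusted over the list alone), with a median of -0.94. H3c1 fell by 1.85 (SE 0.19, adjusted p = 0.000357), H4c3 by 1.85 (SE 0.25, adjusted p = 0.00126), H2bc14 by 1.83 (SE 0.26, adjusted p = 0.00173) and H4c4 by 1.58 (SE 0.23, adjusted p = 0.00190). In camera adjusted p was 4.82e-09, and adjusted p = 0.437 with an estimated correlation, with medians of -0.89 on slide 1, -0.98 on slide 2 and -0.90 with a slide term. Among 45 DNA replication genes 13 fell and 1 rose (14 and 2 when adjusted over the list alone), with a median of -0.21. Pole2, a subunit of DNA polymerase epsilon, fell by 1.05 (SE 0.15, adjusted p = 0.00186), Tk1, the thymidine kinase of S phase, by 0.88 (SE 0.14, adjusted p = 0.00310), Pole by 0.78 (SE 0.13, adjusted p = 0.00401) and Pola1 by 0.69 (SE 0.13, adjusted p = 0.00500). This list had adjusted p = 0.00219 in camera, and adjusted p = 0.534 with an estimated correlation, and medians of -0.15 on slide 1, -0.23 on slide 2 and -0.21 with a slide term. It was lost without WT replicates 1 and 2 (adjusted p = 0.0726).

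Genes of sterol synthesis and glucose use fell as well. Of 23 cholesterol synthesis genes 8 fell and 0 rose (8 and 0 when adjusted over the list alone), with a median of -0.34. Tm7sf2 fell by 1.32 (SE 0.13, adjusted p = 0.000293), Fdps, the farnesyl diphosphate synthase, by 1.26 (SE 0.13, adjusted p = 0.000357), Lss, the lanosterol synthase, by 1.05 (SE 0.15, adjusted p = 0.00191) and Fdft1, the squalene synthase, by 1.00 (SE 0.13, adjusted p = 0.000907). Camera gave adjusted p = 2.38e-05, and adjusted p = 0.437 with an estimated correlation, with medians of -0.40 on slide 1, -0.32 on slide 2 and -0.34 with a slide term. The medians of the list per extract did not separate the genotypes (exact permutation p = 0.171).

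Of 20 glycolysis genes 5 fell and 0 rose (5 and 0 when adjusted over the list alone), with a median of -0.28. Slc16a3, a lactate exporter, fell by 1.36 (SE 0.34, adjusted p = 0.0182), and Pfkp, a phosphofructokinase, by 0.55 (SE 0.14, adjusted p = 0.0189). The glucose transporter Slc2a3 fell by 1.03 (SE 0.31, adjusted p = 0.0389) and the glucose transporter Slc2a1 fell by 0.95 (SE 0.16, adjusted p = 0.00365). In camera adjusted p was 0.00410, and adjusted p = 0.566 with an estimated correlation, with medians of -0.25 on slide 1, -0.32 on slide 2 and -0.28 with a slide term. Pfkp lost its call without Lck-/- replicate 3 (adjusted p = 0.0619) and Slc2a3 without any of 5 extracts, with the highest adjusted p of 0.103 without WT replicate 2. Of 19 ATF4 targets, which serve amino acid supply and the stress response, 8 fell and 0 rose (10 and 0 when adjusted over the list alone), with a median of -0.35. Vldlr fell by 1.52 (SE 0.14, adjusted p = 0.000241), Chac1 by 1.12 (SE 0.23, adjusted p = 0.00825), Atf3 by 0.83 (SE 0.20, adjusted p = 0.0149) and Cebpg by 0.72 (SE 0.15, adjusted p = 0.00926). Vldlr takes up lipoproteins and Chac1 breaks down glutathione. In camera adjusted p was 0.0225, and adjusted p = 0.437 with an estimated correlation, with medians of -0.28 on slide 1, -0.42 on slide 2 and -0.35 with a slide term. The ATF4 call was lost without Lck-/- replicate 2 (adjusted p = 0.0571), and the medians of the list per extract gave an exact permutation p of 1.

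Ribosome biogenesis genes rose. Of 99 measured genes 25 rose and 4 fell (34 and 5 when adjusted over the list alone), with a median of 0.30. Mdn1, an assembly ATPase of the large subunit, rose by 0.89 (SE 0.17, adjusted p = 0.00622), Aen, a nuclease also on the p53 list, by 0.84 (SE 0.12, adjusted p = 0.00148), Nifk by 0.81 (SE 0.14, adjusted p = 0.00423) and Grwd1 by 0.61 (SE 0.11, adjusted p = 0.00577). Dimmer probes read -0.01 for Mdn1 and -0.64 for Grwd1. The list rose in camera with adjusted p = 0.000112, or 0.0280 with an estimated correlation. Its medians were 0.33 on slide 1, 0.28 on slide 2 and 0.30 with a slide term. Among the calls of the 30 lists fixed before the data were examined, in the 4 comparisons between genotypes, only ribosome biogenesis in the mean of both fractions and in the sub-polysomal level held with an estimated correlation.

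Interferon response genes rose by small amounts. Of 23 measured genes 4 rose and 0 fell (4 and 0 when adjusted over the list alone), with a median of 0.33. Usp18, which removes the ubiquitin-like ISG15, rose by 1.27 (SE 0.32, adjusted p = 0.0205), Bst2, which tethers budding virus, by 0.88 (SE 0.19, adjusted p = 0.00997), Oasl1 by 0.74 (SE 0.15, adjusted p = 0.00901) and Gbp4 by 0.52 (SE 0.16, adjusted p = 0.0410). Camera gave adjusted p = 0.0415, and adjusted p = 0.681 with an estimated correlation, with medians of 0.26 on slide 1, 0.35 on slide 2 and 0.33 with a slide term. The list was lost without Lck-/- replicate 2 (adjusted p = 0.155), Lck-/- replicate 3 (adjusted p = 0.0549), Lck-/- replicate 4 (adjusted p = 0.0588), WT replicate 1 (adjusted p = 0.0536) or WT replicate 4 (adjusted p = 0.159). Usp18 lost its call without Lck-/- replicate 4 (adjusted p = 0.0601), and Gbp4 without any of 6 extracts, with the highest adjusted p of 0.110 without Lck-/- replicate 4.

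Of 22 p53 target and apoptosis genes 5 rose and 0 fell (5 and 0 when adjusted over the list alone), with a median of 0.26. Gadd45b rose by 1.23 (SE 0.19, adjusted p = 0.00243), Gadd45g by 0.94 (SE 0.26, adjusted p = 0.0294), Aen, a p53-induced nuclease, by 0.84, and Bcl2l1, whose long form blocks apoptosis, by 0.73 (SE 0.17, adjusted p = 0.0142). The GADD45 proteins act in the stress response. In camera adjusted p was 0.0355, and adjusted p = 0.562 with an estimated correlation, with medians of 0.19 on slide 1, 0.29 on slide 2 and 0.26 with a slide term. The list was lost without Lck-/- replicate 1 (adjusted p = 0.0642), Lck-/- replicate 2 (adjusted p = 0.0694) or WT replicate 3 (adjusted p = 0.0995), and Gadd45g without any of 4 extracts, with the highest adjusted p of 0.0847 without WT replicate 3.

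**Figure D3:**
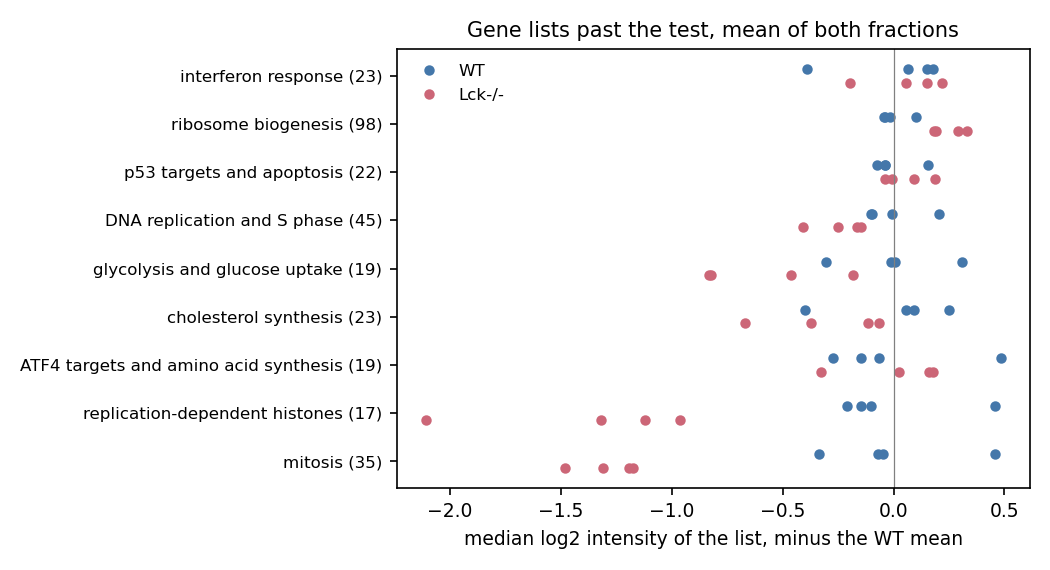
Median log2 intensity of the 9 lists that passed in the mean of both fractions, per extract and minus the WT mean, in WT and Lck-/-; points are extracts, and numbers in brackets are genes with complete values. The mitosis list has a median gene difference of -1.03 and the ribosome biogenesis list 0.30.

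Eomes and Gzmc were among the largest single rises in the mean of both fractions, but the list of cytotoxic effector genes did not pass. Of its 21 measured genes 5 rose and 2 fell, with a median of 0.00 (camera adjusted p = 0.408; exact permutation p = 0.0286 for the medians per extract). Eomes, a T-box factor of effector and memory CD8 T cells and NK cells, rose by 2.06 (SE 0.33, adjusted p = 0.00272) and Gzmc, a granzyme, by 1.75 (SE 0.20, adjusted p = 0.000612). The calcium-binding proteins S100a4 and S100a6 rose by 1.90 (SE 0.18, adjusted p = 0.000241) and 1.90 (SE 0.19, adjusted p = 0.000317). St6galnac2, a sialyltransferase, rose from a WT signal below background, at least 2.73-fold in the polysomal and 3.79-fold in the sub-polysomal fraction (adjusted p = 0.000796). Mid1, a ubiquitin ligase on microtubules, also rose (adjusted p = 0.000179), at least 3.56-fold in the sub-polysomal fraction, where its WT signal lay below background. Ubxn11 rose by 1.86 (SE 0.14, adjusted p = 4.66e-05), Hyi by 1.45 (SE 0.15, adjusted p = 0.000357) and Ralgps1 by 1.32 (SE 0.31, adjusted p = 0.0141). Hba-a2, an alpha chain of haemoglobin and a mark of red cells, rose by 2.16 (SE 0.46, adjusted p = 0.00964), with 13.91, 12.38, 11.73 and 11.07 in the 4 Lck-/- extracts against 9.79 to 10.34 in WT. The list of erythroid markers had too few measured members to be tested (0 to 3).

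The largest falls were of mixed function and included a glycolytic enzyme, a gene of lipid synthesis and genes of division. Aldoc, an aldolase, fell by 2.47 (SE 0.26, adjusted p = 0.000357), Scd2, a stearoyl-CoA desaturase, by 2.16 (SE 0.36, adjusted p = 0.00350) and Cd81, a tetraspanin, by 2.34 (SE 0.29, adjusted p = 0.000818). Rab6b, a Rab GTPase, also fell (adjusted p = 5.76e-06), at least 3.38-fold in the sub-polysomal fraction, where its Lck-/- signal lay below background. Aunip, a partner of Aurora A, fell by 2.12 (SE 0.15, adjusted p = 4.64e-05) and Nusap1, a spindle protein, by 2.09 (SE 0.28, adjusted p = 0.00130). Snhg3, a host of small nucleolar RNAs, fell by 2.08 (SE 0.26, adjusted p = 0.000818). Gnas, the stimulatory G protein alpha subunit, fell by 2.14 (SE 0.28, adjusted p = 0.00116), and other probes of it read -0.22. ND4, a mitochondrially encoded subunit of complex I, fell by 2.34 (SE 0.38, adjusted p = 0.00298). Of 13 mitochondrially encoded mRNAs 8 fell and 0 rose, with a median of -0.88 and an exact permutation p of 0.0286 for the medians per extract.

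**Figure D4:**
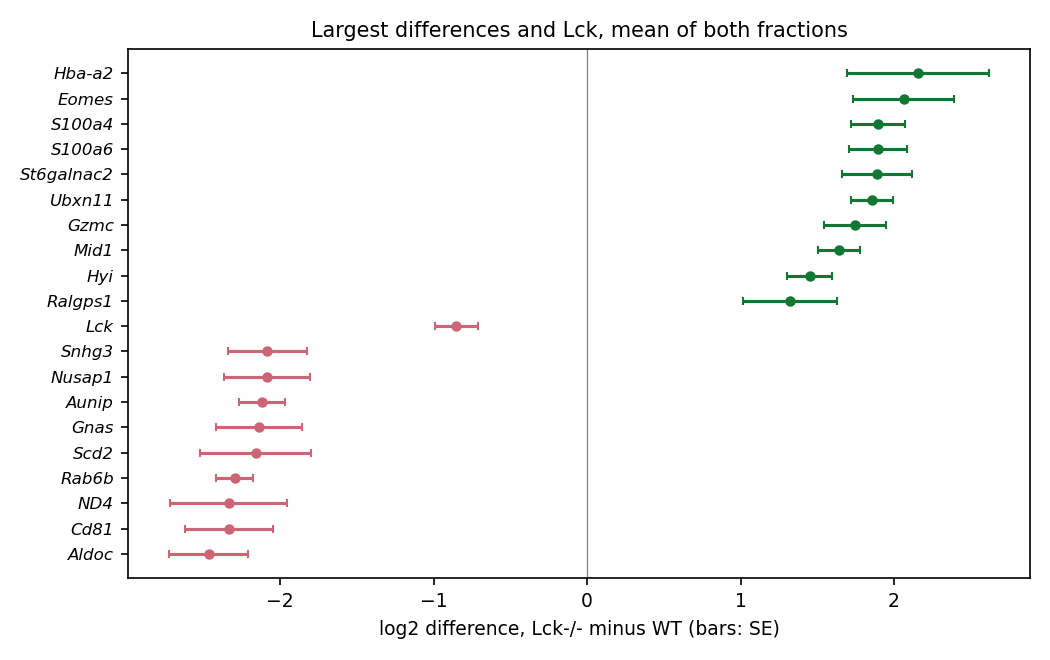
Log2 difference, Lck-/- minus WT, in the mean of both fractions for Lck and 19 genes among the largest rises and falls; points are differences and whiskers ± SE, n = 4 per genotype; WT signal of St6galnac2 and Mid1 and Lck-/- signal of Rab6b lie below background in at least 1 fraction, so their points include background values. Differences range from -2.47 for Aldoc to 2.16 for Hba-a2, with Lck at -0.85.

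In all, 839 of 9075 genes rose and 1025 fell in the mean of both fractions, with 51 rises and 222 falls of at least 2-fold. No overlap was seen in 2333 genes (25.8%, chance 2.86%), 1651 of them called. Centring on the 75th percentile gave 206 rises and 874 falls and ended the calls of Grwd1, Slc2a3, Gadd45g and Gbp4 (adjusted p from 0.0532 to 0.181). On leaving out 1 extract the total of 1864 became 968 without Lck-/- replicate 4, 1082 without Lck-/- replicate 3, 1116 without WT replicate 2 and 1091 without WT replicate 3. Slide 1 alone called 272 rises and 566 falls, slide 2 alone 477 and 667, and all arrays with slide and dye terms 1097 and 1124. The 18 lists that did not pass had adjusted p from 0.0977 for myeloid and dendritic cell markers to 0.980 and medians from -0.19 to 0.32, and 56 of their genes rose and 68 fell. Lists of B cell markers (2 measured), erythroid markers and stromal markers (1 to 2 measured) were not tested in any comparison, nor were NK and CD4 markers in the ratio (4 and 3 measured).

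In the polysomal fraction the same cell division and metabolic lists fell and ribosomal protein mRNAs rose. Of 37 mitosis genes 28 fell and 0 rose (33 and 0 when adjusted over the list alone), with a median of -1.13, at -1.27 on slide 1, -1.05 on slide 2 and -1.13 with a slide term. Ccnb2, a mitotic cyclin, fell by 2.21 (SE 0.26, adjusted p = 0.00101), Ccnb1 by 1.59 (SE 0.19, adjusted p = 0.00101), Cdk1 by 1.45 (SE 0.16, adjusted p = 0.00101) and Bub1 by 1.26 (SE 0.14, adjusted p = 0.00101). Camera gave adjusted p = 7.58e-19, or 0.345 with an estimated correlation. Histone genes fell in 9 of 19 cases and rose in 0 (13 and 0 when adjusted over the list alone), with a median of -0.98, at -0.76 on slide 1, -1.15 on slide 2 and -0.89 with a slide term (camera adjusted p = 2.24e-06, and adjusted p = 0.424 with an estimated correlation). H3c1 fell by 1.69 (SE 0.25, adjusted p = 0.00255). Of 48 replication genes 13 fell and 1 rose (15 and 1 when adjusted over the list alone), with a median of -0.29, at -0.28 on slide 1, -0.28 on slide 2 and -0.29 with a slide term (camera adjusted p = 0.000587, and adjusted p = 0.345 with an estimated correlation). Pole2 fell by 1.23 (SE 0.19, adjusted p = 0.00299).

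Ribosomal protein mRNAs rose on polysomes in 20 of 81 cases and fell in 0 (38 and 0 when adjusted over the list alone), with a median of 0.48, at 0.73 on slide 1, 0.16 on slide 2 and 0.48 with a slide term. In camera adjusted p was 6.15e-12, or 0.395 with an estimated correlation. The median turned to -0.11 with median centring, above the -0.31 of all genes, and the call was lost in processed signals (adjusted p = 0.564). The TOP list rose (camera adjusted p = 0.00838, and adjusted p = 0.424 with an estimated correlation), with 5 of 18 genes up and 2 down (7 and 2 when adjusted over the list alone), a median of 0.54 and medians of 0.40 on slide 1, 0.44 on slide 2 and 0.54 with a slide term. The TOP call was lost with median centring (-0.05, adjusted p = 0.425), in processed signals (adjusted p = 0.384), with quantile normalization (adjusted p = 0.277), with centring on the 75th percentile (adjusted p = 0.0512) and without Lck-/- replicate 1 (adjusted p = 0.0741). Ribosome biogenesis rose with 13 of 102 genes up and 1 down (10 and 1 when adjusted over the list alone), a median of 0.26 and medians of 0.26 on slide 1, 0.24 on slide 2 and 0.26 with a slide term (camera adjusted p = 0.00103, and adjusted p = 0.345 with an estimated correlation), and was lost with median centring (-0.18, adjusted p = 0.111). Nifk rose by 0.86 (SE 0.17, adjusted p = 0.0111) and Grwd1 by 0.75 (SE 0.13, adjusted p = 0.00548), where the mean over the probes of Grwd1 read -0.02.

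Metabolic lists fell on polysomes. Cholesterol synthesis had 9 of 24 genes down and 0 up (10 and 0 when adjusted over the list alone), with a median of -0.48, at -0.52 on slide 1, -0.46 on slide 2 and -0.48 with a slide term (camera adjusted p = 4.52e-06, and adjusted p = 0.345 with an estimated correlation), and Dhcr7, the last enzyme of the pathway, fell by 1.11 (SE 0.16, adjusted p = 0.00239). ATF4 targets had 8 of 20 genes down and 0 up (9 and 1 when adjusted over the list alone), with a median of -0.46, at -0.41 on slide 1, -0.44 on slide 2 and -0.46 with a slide term (camera adjusted p = 0.0199, and adjusted p = 0.395 with an estimated correlation), and Pycr1, an enzyme of proline synthesis, fell by 1.02 (SE 0.18, adjusted p = 0.00548). Glycolysis had 4 of 20 genes down and 0 up (4 and 0 when adjusted over the list alone), with a median of -0.26, at -0.18 on slide 1, -0.32 on slide 2 and -0.26 with a slide term (camera adjusted p = 0.0173, and adjusted p = 0.558 with an estimated correlation), and Slc2a1 fell by 1.03 (SE 0.20, adjusted p = 0.00724). The glycolysis call was lost without Lck-/- replicate 3 (adjusted p = 0.0535) and without WT replicates 1 and 2 (adjusted p = 0.0587). Oxidative phosphorylation had 11 of 76 genes down and 0 up (11 and 0 when adjusted over the list alone), with a median of -0.13, at -0.08 on slide 1, -0.26 on slide 2 and -0.13 with a slide term (camera adjusted p = 0.0241, and adjusted p = 0.395 with an estimated correlation). Atp5j, an ATP synthase subunit, fell by 1.03 (SE 0.17, adjusted p = 0.00370). This list was lost without Lck-/- replicate 2 (adjusted p = 0.146), Lck-/- replicate 4 (adjusted p = 0.0906) or WT replicate 3 (adjusted p = 0.0667).

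Interferon genes rose on polysomes in 3 of 26 cases and fell in 0 (2 and 0 when adjusted over the list alone), with a median of 0.22, at 0.31 on slide 1, 0.19 on slide 2 and 0.22 with a slide term (camera adjusted p = 0.0241, and adjusted p = 0.645 with an estimated correlation). Bst2 rose by 0.88 (SE 0.20, adjusted p = 0.0147; 0.0806 with crossed dye swaps). The interferon median turned to -0.08 with median centring, and the call was lost without Lck-/- replicate 2 (adjusted p = 0.127) or WT replicate 4 (adjusted p = 0.0759). The p53 list had 2 of 23 genes up and 0 down (2 and 0 when adjusted over the list alone), with a median of 0.21, at 0.08 on slide 1, 0.26 on slide 2 and 0.21 with a slide term (camera adjusted p = 0.0241, and adjusted p = 0.424 with an estimated correlation), and Gadd45b rose by 1.18 (SE 0.20, adjusted p = 0.00413). Its call was lost with median centring (-0.19, adjusted p = 0.182), without Lck-/- replicate 1 (adjusted p = 0.0852), Lck-/- replicate 2 (adjusted p = 0.0597) or WT replicate 3 (adjusted p = 0.0843). NK cell markers had 2 of 8 genes up and 0 down (2 and 0 when adjusted over the list alone), with a median of 0.39, at 0.37 on slide 1, 0.29 on slide 2 and 0.39 with a slide term (camera adjusted p = 0.0310, and adjusted p = 0.395 with an estimated correlation). The 2 were Eomes, also a T cell gene, at 2.14 (SE 0.35, adjusted p = 0.00365) and Cd244a, read by a SINE probe, at 0.49 (SE 0.15, adjusted p = 0.0462; 0.169 with crossed dye swaps), while the NK receptors Klra1 and Klra4 stood at 0.41 (SE 0.17, adjusted p = 0.123) and 0.37 (SE 0.20, adjusted p = 0.238). The NK call was lost without SINE probes (adjusted p = 0.0772) and without Lck-/- replicate 1 (adjusted p = 0.0671), Lck-/- replicate 2 (adjusted p = 0.0712), Lck-/- replicate 3 (adjusted p = 0.0844) or WT replicate 1 (adjusted p = 0.0823), and Cd244a was lost without any of 7 extracts, with the highest adjusted p of 0.138 without Lck-/- replicate 4.

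Of 10294 genes tested on polysomes 571 rose and 965 fell, with 127 rises and 263 falls of at least 2-fold. Large falls outside the lists were Aldoc at -2.62 (SE 0.26), Scd2 at -2.41 (SE 0.38), Cd81 at -2.30 (SE 0.27), H2bc1 at -2.09 (SE 0.43), Bnip3, a mitophagy receptor, at -2.07 (SE 0.29) and Egln3, an oxygen-sensing prolyl hydroxylase, at -2.05 (SE 0.26), and large rises Hba-a2 at 2.54 (SE 0.48), Hyi at 2.03 (SE 0.18) and Ubxn11 at 1.88 (SE 0.17). No overlap was seen in 2320 genes (22.6%, chance 2.86%). Median centring gave 50 rises and 2180 falls, with the median of all genes at -0.31 instead of 0.00, and ended the calls of Gadd45b, Bst2, Nifk, Grwd1 and Cd244a (adjusted p from 0.0785 to 0.507). Counts were 191 and 918 with centring on the 75th percentile. Crossed dye swaps gave 204 and 496, and leaving out WT replicates 1 and 2 gave 42 and 210. The total of 1536 became 2459 without Lck-/- replicate 1, 885 without Lck-/- replicate 3, 716 without Lck-/- replicate 4, 1019 without WT replicate 1, 767 without WT replicate 2, 711 without WT replicate 3 and 1021 without WT replicate 4. Slide 1 alone called 19 rises and 68 falls, slide 2 alone 929 and 965, and all arrays with slide and dye terms 770 and 1052. The 14 lists that did not pass had adjusted p from 0.110 for mitochondrial ribosomal proteins to 0.944 and medians from -0.14 to 0.41, and 33 of their genes rose and 40 fell.

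In the sub-polysomal fraction ribosomal protein and mitochondrial mRNAs fell. Of 81 ribosomal protein genes 44 fell and 0 rose (56 and 0 when adjusted over the list alone), with a median of -0.49, at -0.82 on slide 1, -0.22 on slide 2 and -0.49 with a slide term. Rpl31 fell by 1.28 (SE 0.20, adjusted p = 0.00307; 0.0748 with crossed dye swaps), Rps7 by 1.26 (SE 0.20, adjusted p = 0.00318) and Rps25 by 0.98 (SE 0.14, adjusted p = 0.00219). Camera gave adjusted p = 3.59e-18, or 0.404 with an estimated correlation. The median turned to 0.08 with median centring and to 0.04 with quantile normalization, and the call was lost with the latter (adjusted p = 0.702) and in processed signals (adjusted p = 0.0728). In the TOP list 6 of 18 genes fell and 1 rose (8 and 1 when adjusted over the list alone), with a median of -0.35, at -0.50 on slide 1, -0.22 on slide 2 and -0.35 with a slide term (camera adjusted p = 0.0120, and adjusted p = 0.467 with an estimated correlation). Eif3e and Eif3f, subunits of an initiation factor, fell by 1.66 (SE 0.26, adjusted p = 0.00286) and 1.48 (SE 0.30, adjusted p = 0.00750), and the TOP RNA Gas5 by 1.55 (SE 0.19, adjusted p = 0.000999). The TOP median turned to 0.25 with median centring (adjusted p = 0.164), 0.10 with quantile normalization (adjusted p = 0.938) and 0.03 in processed signals (adjusted p = 0.730). Of 13 mitochondrially encoded mRNAs 12 fell, with a median of -1.73 (exact permutation p = 0.0286). ND4 fell by 3.27 (SE 0.59, adjusted p = 0.00504) and ND1 fell by 2.81 (SE 0.57, adjusted p = 0.00769). On polysomes 2 of the 13 rose and 3 fell, with a median of -0.06 (exact permutation p = 0.743). These medians depended on scaling: with median centring, quantile normalization and centring on the 75th percentile they were -1.20, -1.13 and -1.89 in the sub-polysomal fraction and -0.56, -0.15 and -0.20 on polysomes.

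Cell division genes fell here as well. Of 35 mitosis genes 25 fell and 0 rose (29 and 1 when adjusted over the list alone), with a median of -0.88, at -0.84 on slide 1, -0.98 on slide 2 and -0.88 with a slide term (camera adjusted p = 2.92e-15, and adjusted p = 0.404 with an estimated correlation). Cenpa, the histone of centromeres, fell by 2.10 (SE 0.27, adjusted p = 0.00132) and Anln by 1.36 (SE 0.15, adjusted p = 0.000565). Of 20 histone genes 14 fell and 0 rose (17 and 0 when adjusted over the list alone), with a median of -1.0, at -1.18 on slide 1, -1.02 on slide 2 and -0.99 with a slide term (camera adjusted p = 1.13e-10, and adjusted p = 0.239 with an estimated correlation), and H3c3 fell by 1.63 (SE 0.17, adjusted p = 0.000402). Of 45 replication genes 10 fell and 1 rose (11 and 1 when adjusted over the list alone), with a median of -0.14, at -0.03 on slide 1, -0.21 on slide 2 and -0.14 with a slide term (camera adjusted p = 0.0135, and adjusted p = 0.546 with an estimated correlation), and Tk1 fell by 0.95 (SE 0.15, adjusted p = 0.00287). The replication median turned to 0.36 with median centring (adjusted p = 0.319), and the call was lost without Lck-/- replicate 2 (adjusted p = 0.0630), without WT replicate 1 (adjusted p = 0.0580) and without WT replicates 1 and 2 (adjusted p = 0.262).

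Ribosome biogenesis rose in the sub-polysomal fraction, with 29 of 99 genes up and 5 down (41 and 5 when adjusted over the list alone), a median of 0.30 and medians of 0.34 on slide 1, 0.26 on slide 2 and 0.30 with a slide term. In camera adjusted p was 3.71e-05, or 0.0190 with an estimated correlation. Fbl, the fibrillarin of the nucleolus, rose by 0.99 (SE 0.17, adjusted p = 0.00450), while Utp6 and Exosc2, both read by SINE probes, stood at -1.29 (SE 0.21, adjusted p = 0.00334) and -1.23 (SE 0.21, adjusted p = 0.00384). Interferon genes rose in 6 of 28 cases and fell in 0 (9 and 0 when adjusted over the list alone), with a median of 0.27, at 0.23 on slide 1, 0.38 on slide 2 and 0.27 with a slide term (camera adjusted p = 0.0113, and adjusted p = 0.546 with an estimated correlation), and Usp18 rose by 1.44 (SE 0.26, adjusted p = 0.00508). The p53 list had 5 of 22 genes up and 0 down (8 and 1 when adjusted over the list alone), with a median of 0.29, at 0.32 on slide 1, 0.27 on slide 2 and 0.29 with a slide term (camera adjusted p = 0.0259, and adjusted p = 0.408 with an estimated correlation), and Gadd45b rose by 1.28 (SE 0.21, adjusted p = 0.00363). The interferon call was lost with median centring (adjusted p = 0.0985), without Lck-/- replicate 2 (adjusted p = 0.0630) or WT replicate 4 (adjusted p = 0.0561), and the p53 call with quantile normalization (adjusted p = 0.0544) and without WT replicate 3 (adjusted p = 0.0604).

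Glycolysis fell with 3 of 20 genes down and 0 up (2 and 0 when adjusted over the list alone), a median of -0.30 and medians of -0.30 on slide 1, -0.30 on slide 2 and -0.30 with a slide term (camera adjusted p = 0.00143, and adjusted p = 0.467 with an estimated correlation), and Slc2a1 fell by 0.87 (SE 0.15, adjusted p = 0.00407). Its median turned to 0.24 with median centring (adjusted p = 0.0985), and the call was lost in processed signals (adjusted p = 0.0728) and with quantile normalization (adjusted p = 0.0562). Cholesterol synthesis had 7 of 23 genes down and 0 up (7 and 0 when adjusted over the list alone), with a median of -0.32, or 0.06 with median centring, at -0.37 on slide 1, -0.25 on slide 2 and -0.32 with a slide term (camera adjusted p = 0.000271, and adjusted p = 0.408 with an estimated correlation), and Fdps fell by 1.35 (SE 0.12, adjusted p = 0.000229). ATF4 targets had 4 of 19 genes down and 0 up (7 and 0 when adjusted over the list alone), with a median of -0.19, at -0.10 on slide 1, -0.28 on slide 2 and -0.19 with a slide term (camera adjusted p = 0.0259, and adjusted p = 0.408 with an estimated correlation), and Chac1 fell by 1.50 (SE 0.26, adjusted p = 0.00451). The ATF4 median turned to 0.34 with median centring (adjusted p = 0.0995), and the call was lost without Lck-/- replicate 2 (adjusted p = 0.0630).

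Of 9704 genes tested in the sub-polysomal fraction 832 rose and 1044 fell, with 47 rises and 261 falls of at least 2-fold. Cxcr6, a chemokine receptor of effector T cells, rose by 1.46 (SE 0.16, adjusted p = 0.000565) and S100a6 by 2.22 (SE 0.19, adjusted p = 0.000163). Mid1 rose from a WT signal below background, at least 3.56-fold (adjusted p = 3.69e-05). Snhg3 fell by 2.88 (SE 0.30, adjusted p = 0.000404) and the long non-coding RNA Lockd fell by 2.23 (SE 0.23, adjusted p = 0.000480). No overlap was seen in 2494 genes (25.8%, chance 2.86%). Median centring gave 3546 rises and 332 falls, with the median of all genes at 0.36 instead of 0.05, and ended the calls of Slc2a1, Rps7, Utp6, Tk1, Rps25 and Exosc2 (adjusted p from 0.0527 to 0.128). Counts were 308 and 860 with centring on the 75th percentile. Crossed dye swaps gave 408 and 657, leaving out WT replicates 1 and 2 gave 399 and 676. Slide 1 alone called 1162 rises and 1266 falls, slide 2 alone 42 and 129, and all arrays with slide and dye terms 1012 and 1142. The total of 1876 became 997 without Lck-/- replicate 3, 1056 without Lck-/- replicate 4, 1240 without WT replicate 2 and 1209 without WT replicate 3. The 16 lists that did not pass had adjusted p from 0.0566 for the proteasome to 0.936 and medians from -0.13 to 0.51, and 65 of their genes rose and 51 fell.

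The last question is which RNAs sat on polysomes in WT cells. Relative to the typical mRNA, Ncl, the nucleolar protein nucleolin, had the highest ratio at 2.24 (SE 0.16, adjusted p = 2.17e-06), with Pfdn6 and Cct8, subunits of the chaperones prefoldin and CCT, at 1.99 (SE 0.19, adjusted p = 1.10e-05) and 1.73 (SE 0.13, adjusted p = 3.14e-06). The RNA-binding proteins Snrpb, Ssb, G3bp2 and Srp54a followed at 1.92 (SE 0.13), 1.83 (SE 0.26), 1.77 (SE 0.14) and 1.76 (SE 0.18), with Rtn3 at 1.80 (SE 0.18), Ndufc2 at 1.76 (SE 0.12) and the pseudogene Smarca5-ps at 1.87 (SE 0.17). RNAs that cytosolic ribosomes do not translate had the lowest ratios. These were the small nuclear RNAs Rnu1b6 at -6.09 (SE 0.26, adjusted p = 1.20e-07) and Rnu2-10 at -5.08 (SE 0.25), the RNase MRP component Rmrp at -6.02 (SE 0.16), the small nucleolar RNAs Rnu3b1 at -5.04 (SE 0.20) and Snora74a at -4.89 (SE 0.12), and the mitochondrially encoded ND3 at -4.71 (SE 0.19), ATP8 at -4.67 (SE 0.22), ATP6 at -4.51 (SE 0.27), COX2 at -4.41 (SE 0.25) and ND1 at -3.95 (SE 0.33).

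In WT 2769 genes lay above 0 and 2378 below, and in Lck-/- 2226 and 2414. These splits follow the scaling. In WT they were 6675 and 295 with median centring, 7436 and 200 without normalization and 7816 and 123 in the authors' ratios. For Lck-/- the same settings gave 2113 and 522, 4696 and 349, and 4693 and 285.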

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

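The tests of SINE probes, of genes chosen or matched on the WT ratio, of crossed dye swaps and of arrays on a shared slide were chosen after the results were seen, and the random splits and the rule for values that stand apart before. Of 562 groups of 4 extracts or arrays, 40 (7.12%) held a value that stood apart from the other 3 by Dixon's test, where chance puts 1 in 20 (5%) past it. Median red intensity was 320.1 and the polysomal channel had 50776 probes above background on the Cy5-polysomal array of Lck-/- replicate 1. The sub-polysomal channel had 30976 probes on the Cy3-polysomal array of Lck-/- replicate 4, and 0.991% of spots were pixel outliers on that of WT replicate 1.

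Several list medians stood apart in 1 extract. In Lck-/- replicate 2 the ribosomal protein list stood at -1.03 in the ratio and 15.84 on polysomes. WT replicate 3 stood at 0.30 for mitosis in the ratio, 14.32 and 14.27 for histones in the mean of both fractions and on polysomes, and 10.31 for cholesterol synthesis on polysomes. The p53 list of WT replicate 4 stood at 10.91 in the mean of both fractions and the glycolysis list of Lck-/- replicate 4 at 13.39 in the sub-polysomal fraction.

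Single genes stood apart as well. In the ratio these were Lck (0.55) and Rps10 (-0.85) in Lck-/- replicate 2, and Sf3b6 (0.25) and Atp5j (0.63) in WT replicate 4. In the mean of both fractions they were Gzmc (7.56) in WT replicate 1, ND4 (14.27) and H2bc14 (14.53) in WT replicate 3, Nusap1 (8.73), Tk1 (11.97) and Espl1 (7.94) in Lck-/- replicate 1, Pole (10.96) in Lck-/- replicate 2, H3c1 (10.36) in Lck-/- replicate 3 and Cd81 (7.59) in Lck-/- replicate 4. On polysomes they were Scd2 (13.09) and H2bc14 (14.66) in WT replicate 3, Nusap1 (8.67) in Lck-/- replicate 1, Atf3 (9.31) in Lck-/- replicate 2, Ccnb2 (7.13) in Lck-/- replicate 3 and Cd81 (7.62) in Lck-/- replicate 4. In the sub-polysomal fraction they were Gzmc (7.34) in WT replicate 1, Lockd (12.10), Gnas (13.00) and Cenpa (10.40) in WT replicate 3, St6galnac2 (6.52) and Chac1 (13.46) in WT replicate 4, Tk1 (11.95) and Rfc3 (7.78) in Lck-/- replicate 1, and Pfkl (9.80) in Lck-/- replicate 4.

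With dye swaps as labelled, random grouping of the extracts argues against chance for the counts. Among the 35 splits of the 8 extracts into 4 and 4, only 1, the genotypes, called as many genes in the ratio (319, highest other 0), the mean of both fractions (1864, highest other 0), the polysomal level (1536, highest other 0) and the sub-polysomal level (1876, highest other 0). With crossed dye swaps the genotype split of the ratio called 40 genes and the highest other split 26, so 1 of 35 reached the count, by a narrower margin.

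RNAs with low polysomal ratios in WT lay higher in Lck-/-. Detected SINE sequence does not account for the 178 of 231 labelled rises read by probes without it. It does not account for the mitochondrial mRNAs, whose probes hold none (exact permutation p = 0.0286, labelled or crossed). Weaker matches may go undetected. With crossed dye swaps those 178 kept their median difference (1.09, from 1.08) while their median SD in WT rose from 0.23 to 0.58. Then 10 of the 40 rises still called came from such probes, and 0 genes passed without SINE probes. Ratios spread less over genes in Lck-/-: SD was 0.53 to 0.72 per array, and 0.75 to 0.97 in WT. Means over extracts were 0.59 against 0.73 (exact permutation p = 0.0571), or 0.81 crossed (exact permutation p = 0.0286). Whether other protein-coding genes shared this cannot be told. Those below -1 in WT replicates 3 and 4 had a median difference of 0.17 from WT replicates 1 and 2 (quartiles -0.06 and 0.50). Using the same 4 extracts for both gave 0.45, which selection inflates. Spread of untranslated RNA into the polysomal pool was not tested.

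Ribosomal protein mRNAs lay higher in the Lck-/- ratio. These genes exceeded protein-coding genes of the same WT ratio by a median of 0.72 (quartiles over genes 0.49 and 0.96). Matching used WT replicates 3 and 4 and the difference only WT replicates 1 and 2, which disagree when crossed. So whether a narrower spread explains the rise cannot be told. Crossed, the medians per extract gave an exact permutation p of 0.143, so the exchange could weaken the result. WT replicate 1 then stood at -2.22 and WT replicate 2 at -0.205, above the highest Lck-/- extract at -0.209, so the genotypes overlapped. The list median of 1.62 on slide 1 against 0.40 on slide 2 comes largely from the arrays labelled as WT replicates 1 and 2, whose medians averaged -2.24 on slide 1 and -0.26 on slide 2: with means of array medians Lck-/- minus WT was 1.57 and 0.25, and 1.27 and 0.76 without these arrays.

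The dye-swap arrays of WT replicates 1 and 2 opposed the arrays they are labelled with. Exchanged labels or hybridisations could produce this, as the lower of the 2 crossed correlations was 0.87, while no own pair of the other extracts exceeded 0.85. A slide effect is argued against by the other 14 pairs of arrays sharing slide and genotype, with a median correlation of -0.27 and a highest of 0.37. The authors' columns matching WT replicates 1 and 2 correlated better with the labelled pairing (r 0.965 and 0.988) than with the crossed pairing (0.912 and 0.918), so the authors may have averaged the arrays as labelled. Whether arrays were exchanged, and which, cannot be told from these files.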

How the results depend on the processing

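These alternatives bound how far the counts and calls reach, and the cause was not tested for any change between settings. Calls of lists stayed the same in 99 of 108 list settings for the ratio, 211 of 225 for the mean of both fractions, 292 of 324 on polysomes and 252 of 275 in the sub-polysomal fraction. A filter for probes well above background on all 16 arrays weakened 9 of 36 list calls: the ATF4, interferon and p53 lists each lost their call in the mean of both fractions (adjusted p = 0.159, 0.207 and 0.0947), on polysomes (0.0984, 0.258 and 0.124) and in the sub-polysomal fraction (0.232, 0.194 and 0.0706). Cy5-polysomal arrays alone weakened 6 of 37: mitosis in the ratio (adjusted p = 0.320), interferon in the mean of both fractions (0.0551), and oxidative phosphorylation (0.258), glycolysis (0.0553), interferon (0.0553) and NK markers (0.106) on polysomes. Cy3-polysomal arrays alone weakened ATF4 targets in the sub-polysomal fraction (0.0611). Named genes kept their call in 815 of 1134 settings for the ratio (257 weaker, 48 stronger, 14 reversed), 1532 of 1604 for the mean of both fractions (71 weaker, 1 reversed), 1710 of 2006 on polysomes (278 weaker, 14 stronger, 4 reversed), 1630 of 1775 in the sub-polysomal fraction (136 weaker, 8 stronger, 1 reversed) and all 596 for the WT ratio. The extracts carry no pairing by number: correlations of same-numbered WT and Lck-/- extracts after removing genotype means were 0.06, -0.17, 0.26 and -0.24 for the ratio and -0.07, -0.09, 0.43 and -0.21 for the mean of both fractions. With the replicate number as a block 178 genes passed for the ratio, 1502 for the mean of both fractions, 1386 on polysomes and 1139 in the sub-polysomal fraction.

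Of the planned settings for the ratio, 133 genes passed with Agilent processed signals, 179 with scale normalization, 202 without the filter, 36 and 30 with the Cy5-polysomal or Cy3-polysomal arrays alone, 2017 with array weights, 188 on slide 1 and 37 on slide 2, 0 with the covariate (1440 with unadjusted p below 0.05), 4715 with median centring and 7452 in the authors' ratios. Of the settings added after the data were examined, 733 passed with the authors' columns centred, 5987 without normalization, 40 with crossed dye swaps, 85 without WT replicates 1 and 2, and 0 with crossed dye swaps and no SINE probes (705 with unadjusted p below 0.05).

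In the mean of both fractions 1080 passed with centring on the 75th percentile, 987 with Cy5-polysomal arrays, 965 with Cy3-polysomal arrays, 5060 with array weights, 838 on slide 1, 1144 on slide 2 and 830 without WT replicates 1 and 2. On polysomes 163 passed with Cy5-polysomal arrays, 329 with Cy3-polysomal arrays, 4071 with array weights, 87 on slide 1, 700 with crossed dye swaps, 252 without WT replicates 1 and 2, and 661 with crossed dye swaps and no SINE probes. In the sub-polysomal fraction 3878 passed with median centring, 1168 with centring on the 75th percentile, 715 with Cy5-polysomal arrays, 491 with Cy3-polysomal arrays, 5292 with array weights, 171 on slide 2, 1065 with crossed dye swaps, 1075 without WT replicates 1 and 2, and 1022 with crossed dye swaps and no SINE probes.

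The WT ratio passed in 3032 genes with Cy5-polysomal arrays and 7939 in the authors' ratios. The Lck-/- ratio passed in 2635 with median centring, 2296 with Cy5-polysomal arrays, 2800 on slide 1, 2968 with crossed dye swaps and 2932 with crossed dye swaps and no SINE probes. The overall ratio differed by -0.72 with Cy5-polysomal arrays, -0.76 on slide 1 and -0.88 on slide 2. Over all probes, mostly without signal, it differed by 0.0012 (authors' ratios -0.11).

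Leaving out each extract in turn gave 103 to 445 genes for the ratio (highest without Lck-/- replicate 2), 968 to 2273 for the mean of both fractions (highest without Lck-/- replicate 1), 711 to 2459 on polysomes, 997 to 1960 in the sub-polysomal fraction, 4492 to 5572 for the WT ratio and 3765 to 4884 for the Lck-/- ratio. The overall ratio ranged from -0.91 to -0.69.

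Directions turned in a few settings. Lck in the ratio read 0.11 on slide 2 and 0.76 with the covariate. In the authors' ratios Rps25 read -0.023, Rps10 -0.42, Rpl12 -0.064, Tpt1 -0.24, Eef1g -0.46, Rack1 -0.77 and Pabpc1 -0.28. Eef1g and Rack1 read -0.11 and -0.37 with median centring and -0.12 and -0.38 without normalization, and Rack1 -0.15 with processed signals. Grwd1 read -0.016 in the mean of both fractions and -0.022 on polysomes with the mean over probes. On polysomes Milr1 read -0.28 without SINE probes, with labelled or crossed dye swaps, and Rack1 -0.049 with median centring. With quantile normalization of the sub-polysomal fraction Tpt1 read 0.10 and the TOP list had adjusted p = 0.938 in the other direction.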

Other observations

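The list of HIF-1 targets was written after the first results were seen and its direction was predicted before it was tested. HIF-1 is the transcription factor that responds to low oxygen and, in activated T cells, to receptor signalling. Targets outside the fixed lists and the named genes fell in Lck-/- cells in the mean of both fractions: of 20 measured genes 12 fell, 0 rose and 19 lay lower, with a median of -0.65. P4ha2, a collagen prolyl hydroxylase, fell by 1.58, and the mitophagy receptor Bnip3l fell by 1.25. Selenbp1 fell by 1.40, the transcription factor Nfil3 by 1.12, Ndrg1 by 1.01 and Vegfa, the vascular growth factor, by 0.82. Camera gave p = 4.29e-08 with the preset correlation and p = 0.0503 with an estimated correlation, and the medians per extract gave an exact permutation p of 0.0286. On polysomes 13 of 27 genes fell (p = 5.6e-09, and p = 0.033 with an estimated correlation), and in the sub-polysomal fraction 12 of 22 (p = 1.7e-07, and p = 0.0445 with an estimated correlation).

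Not every target moved. Of 12 HIF-1 targets on the glycolysis list 3 fell in the mean of both fractions: Slc2a3 by 1.03, Slc2a1 by 0.95 and Pfkl by 0.59 (adjusted p = 0.0389, 0.00365 and 0.0437). The other 9 did not pass and stood between -0.59 and 0.32, with Ldha at 0.32, Pgk1 at -0.30, Gapdh at -0.04 and Hk2 at -0.13. Among targets outside that list but among the named genes, Bnip3 fell by 1.91 (SE 0.27) and Egln3 by 1.83 (SE 0.22).

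A hypothesis is that lower HIF-1 activity in Lck-/- cells could underlie the falls of Aldoc and of the glycolysis list. The camera p of 4.29e-08 for targets outside the fixed lists fits it, but the p of 0.0503 with an estimated correlation does not pass. Fewer dividing cells or less activated cells at 24 h might lower the same genes, and protein or oxygen measurements, which the series does not hold, would be needed to separate these.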
